A study of Rattus norvegicus with 18 samples.

How the data were processed

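The deposited table holds 1 value per probe set and array, deposited as intensity on a linear scale. Array medians and quartiles lay close together, as after a normalization between arrays; the normalization method is not given in the sources used here. Lowest and highest values were 18.97 and 29640. The upper quartile of an array lay between 639.9 and 715.2, and the values were used as deposited, without further normalization, as log2(intensity + 16). Affymetrix control probe sets (57) were left out, and all other 31042 were tested without a filter. Of these, 20826 carried 1 gene symbol, 436 several and 9780 none, for 14217 named genes. Symbols were compared with a RefSeq gene table, where 20758 of the probe sets with 1 symbol were found and 0 were updated. Whether any probes detect the introduced constructs was not examined.

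Groups and replicate numbers came from the labels, and all 18 arrays entered 1 linear model in limma with a mean for each of the 6 groups. Contrasts were tested with limma's moderated test (eBayes), with Benjamini-Hochberg adjustment over all tested probe sets within each contrast. Residuals had 12 degrees of freedom, with a prior of 2.89, and the median residual SD was 0.10 log2 units (0.09 with the replicate block). An induction is the change from 0 h in MEF2-VP16-ER neurons minus that in control neurons. Contrasts, alternatives, gene lists and the rule for naming genes were set before the data were examined.

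Genes named in the text come from probe sets with 1 symbol, each gene counted once by its smallest adjusted p. Among those with adjusted p under 0.05 and groups that do not overlap, the largest changes are named: up to 18 higher and 10 lower at 2.5 h, 12 and 6 at 1 h, 10 and 10 at 0 h, 6 and 6 in control neurons, and 5 and 5 for the difference between the times. Up to 4 members of each list, and always Mef2a, Mef2c, Mef2d, Nr4a1, Arc, Bdnf and Homer1, are also named.

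The 26 gene lists were written from general knowledge and hold 605 entries, of which 542 were measured; the other 63 were not analysed here. Each gene was represented by its probe set with the highest mean, and lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists within a contrast. Camera with the correlation estimated from the residuals was an alternative.

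Replicate numbers were checked as a pairing: residuals of arrays with the same number were correlated above 0.1 in 44 of 45 pairs. The lowest correlation was 0.068, between MEF2-VP16-ER at 0 h and 1 h in replicate 2, so the comparisons at 1 h with MEF2-VP16-ER were not treated as paired. That rule turned on this pair alone. Each of the 18 arrays was most closely correlated with an array of its own number, so a pairing at 1 h is not excluded. For each other comparison the result with replicate number as a block is given where it changes a count or call. The main fit of every comparison had no block. Its counts, and the genes said to have changed or not, therefore leave this pairing out.

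Alternatives tried were quantile normalization, median centring, pseudocounts of 1 and 64, only probe sets above the median level, 1 probe set per gene, eBayes with trend and robust, only the groups of a contrast in the fit, the same time point without the 0 h difference, the replicate block, and leaving out single arrays or a replicate number. For lists, the mean over all probe sets of a gene was also tried, and the block together with an estimated correlation was added after the values were seen. The steps were tested on simulated data with known changes over 31042 probe sets: at 2.5 h, 39 of 40 probe sets changed by 2 log2 units, 65 of 80 changed by 1 and 11 of 80 changed by 0.5 were found, with 3 false calls. With the replicate block 39, 79 and 32 of these were found, with 7 false calls, so the main fit missed more of the smaller changes. The changed probe sets were drawn from those above the median level. Of 20 unchanged simulated lists 0 were called. Their members were drawn at random, with noise independent between probe sets apart from replicate effects. Members of a real list may move together, so the simulated lists cannot show how often such a list is called wrongly. Small-sample p values for RNA integrity and for single lists are exact permutation p values. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.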

Results

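Gene expression was measured on 18 Affymetrix arrays hybridised with labelled RNA from rat hippocampal neurons kept in culture. The neurons had received a lentivirus on day 3, and 4-hydroxytamoxifen (4OHT) was added on day 10 for 0, 1 or 2.5 h. One virus carried MEF2-VP16-ER, a form of the transcription factor MEF2 that is fused to the VP16 activation domain and to a ligand-binding domain of the estrogen receptor. The control virus carried the same fusion without the DNA-binding domain. Each of the 6 groups held 3 biological replicates, per the labels. Values are deposited intensities on a linear scale, and the median of an array lay between 190.3 and 196.9. Changes are differences of log2(intensity + 16), a scale that understates the change of dim genes. The median SE of an induction was 0.12 log2 units, and the number of arrays limited the precision. A gene is said to have risen, fallen or changed only where its limma adjusted p was under 0.05 over all 31042 probe sets.

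The comparison at 2.5 h asked which genes changed in MEF2-VP16-ER neurons beyond the change in control neurons: the 2.5 h minus 0 h difference in the former, minus the same difference in the latter. In this comparison, rose and fell refer to that difference. Hs3st1, which encodes a heparan sulfate sulfotransferase, had the largest called induction, 2.40 ± 0.16 log2 units (SE, 3 arrays in each of 4 groups, fold 5.28, adjusted p = 4.01e-06). Its change was 1.60 in MEF2-VP16-ER neurons and -0.80 in control neurons, the latter not called without the replicate block. By the rise in MEF2-VP16-ER neurons alone Hs3st1 did not lead (below). Its mean intensity went from 503 ± 0.94 at 0 h (SD, n = 3) to 1556 ± 97.8 at 2.5 h with MEF2-VP16-ER, and from 488 ± 21.9 to 276 ± 50.2 in control neurons. Col10a1, the gene of a collagen of growing cartilage, rose by 2.39 ± 0.26 (adjusted p = 0.00107), from an intensity of 63.4 ± 0.87 to 425 ± 144. Rgs2, a regulator of G-protein signalling, rose by 2.11 ± 0.25 (adjusted p = 0.00149), from 912 ± 113 to 3898 ± 863, and its other probe set also rose. Bambi, a membrane protein that dampens TGF-beta family signalling, rose by 1.75 ± 0.15 (adjusted p = 9.37e-05). Gse1 (-1.19 ± 0.15, adjusted p = 0.00204) and Nin (-1.07 ± 0.17, adjusted p = 0.0146), whose product sits at the centrosome, fell the most among probe sets with a gene name.

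Further genes rose by more than 1 log2 unit. Pwwp3b rose by 2.29 ± 0.28 (adjusted p = 0.00204), the tyrosine phosphatase gene Ptpn21 by 1.99 ± 0.29 (adjusted p = 0.00791) and the opsin gene Opn3 by 1.71 ± 0.27 (adjusted p = 0.0146). Among regulators of transcription, Cited2 rose by 1.56 ± 0.20 (adjusted p = 0.00315; its other probe set by 1.82), the homeobox gene Gbx2 by 1.45 ± 0.17 (adjusted p = 0.00149), Mitf by 1.19 ± 0.22 (adjusted p = 0.0454) and the nuclear receptor gene Nr4a1 by 1.11 ± 0.19 (adjusted p = 0.0299). Inhba, which encodes an activin subunit, rose by 1.45 ± 0.25 (adjusted p = 0.0264), the potassium channel gene Kcna4 by 1.42 ± 0.22 (adjusted p = 0.0149), Rgs3 by 1.37 ± 0.24 (adjusted p = 0.0294) and Spry1, an inhibitor of Ras-MAPK signalling, by 1.28 ± 0.21 (adjusted p = 0.0232). Gask1b (1.36 ± 0.13, adjusted p = 0.000237), Zfp46 (1.19 ± 0.16, adjusted p = 0.00413) and B3gnt2 (1.06 ± 0.15, adjusted p = 0.00675) also rose. The other falls named by the rule were smaller: Kcnk1 -0.82, Dyrk3 -0.82, Lrtm2 -0.74, Slc35e4 -0.71, Pfkfb3 -0.71, Traip -0.64, Zfp467 -0.62 and Prag1 -0.56. The probe sets of some of these genes differed: they spanned 0.23 to 1.45 for Gbx2, 0.01 to 1.45 for Inhba, -0.07 to 1.37 for Rgs3, 0.36 to 1.36 for Gask1b, 0.37 to 1.19 for Mitf, -0.05 to 1.06 for B3gnt2, -1.19 to 0.24 for Gse1 and -0.71 to 0.02 for Pfkfb3. Of the probe sets without a gene name, 9 rose, that with the smallest p by 1.56 ± 0.11 (adjusted p = 4.01e-06), and 1 fell (-1.42, adjusted p = 0.0234).

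In all, limma called 55 of 31042 probe sets at 2.5 h, 43 higher and 12 lower, which named 32 genes that rose and 11 that fell; 24 of the rises and 3 of the falls were at least 2-fold. At unadjusted p under 0.05 there were 1485 probe sets, where 1552 are expected for uniform p values. The comparisons within control neurons had only 667 and 840, far under 1552. The expected number is therefore no sound yardstick here, and 1485 does not show that the induction was no larger than chance. With the replicate number as a block the count was 291 (175 higher, 116 lower), and all 55 were among them. Without control 0 h replicate 1 the count was 31, without control 0 h replicate 2 it was 33, without control 2.5 h replicate 2 it was 36, without MEF2-VP16-ER 0 h replicate 2 it was 32 and without MEF2-VP16-ER 0 h replicate 3 it was 30. Hs3st1, Col10a1, Pwwp3b, Rgs2, Ptpn21, Bambi, Cited2, Gbx2, Gask1b, Zfp46, B3gnt2, Gse1 and Zfp467 kept the call when any single array of the 12 was left out. Opn3 lost it without control 0 h replicate 1 (adjusted p = 0.0506), Kcna4 without MEF2-VP16-ER 0 h replicate 3 (adjusted p = 0.0586) and Nin without MEF2-VP16-ER 0 h replicate 2 (adjusted p = 0.0503). Inhba, Rgs3 and Spry1 kept the call in 5 of the 12 fits, Dyrk3 and Slc35e4 in 4, Mitf, Nr4a1, Kcnk1, Lrtm2 and Prag1 in 2, and Pfkfb3 and Traip in 1. Leaving out all arrays of replicate 2 removed more calls. Of the genes named for this comparison, only Hs3st1, Col10a1, Bambi and Gask1b were then still called.

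**Figure D1:**
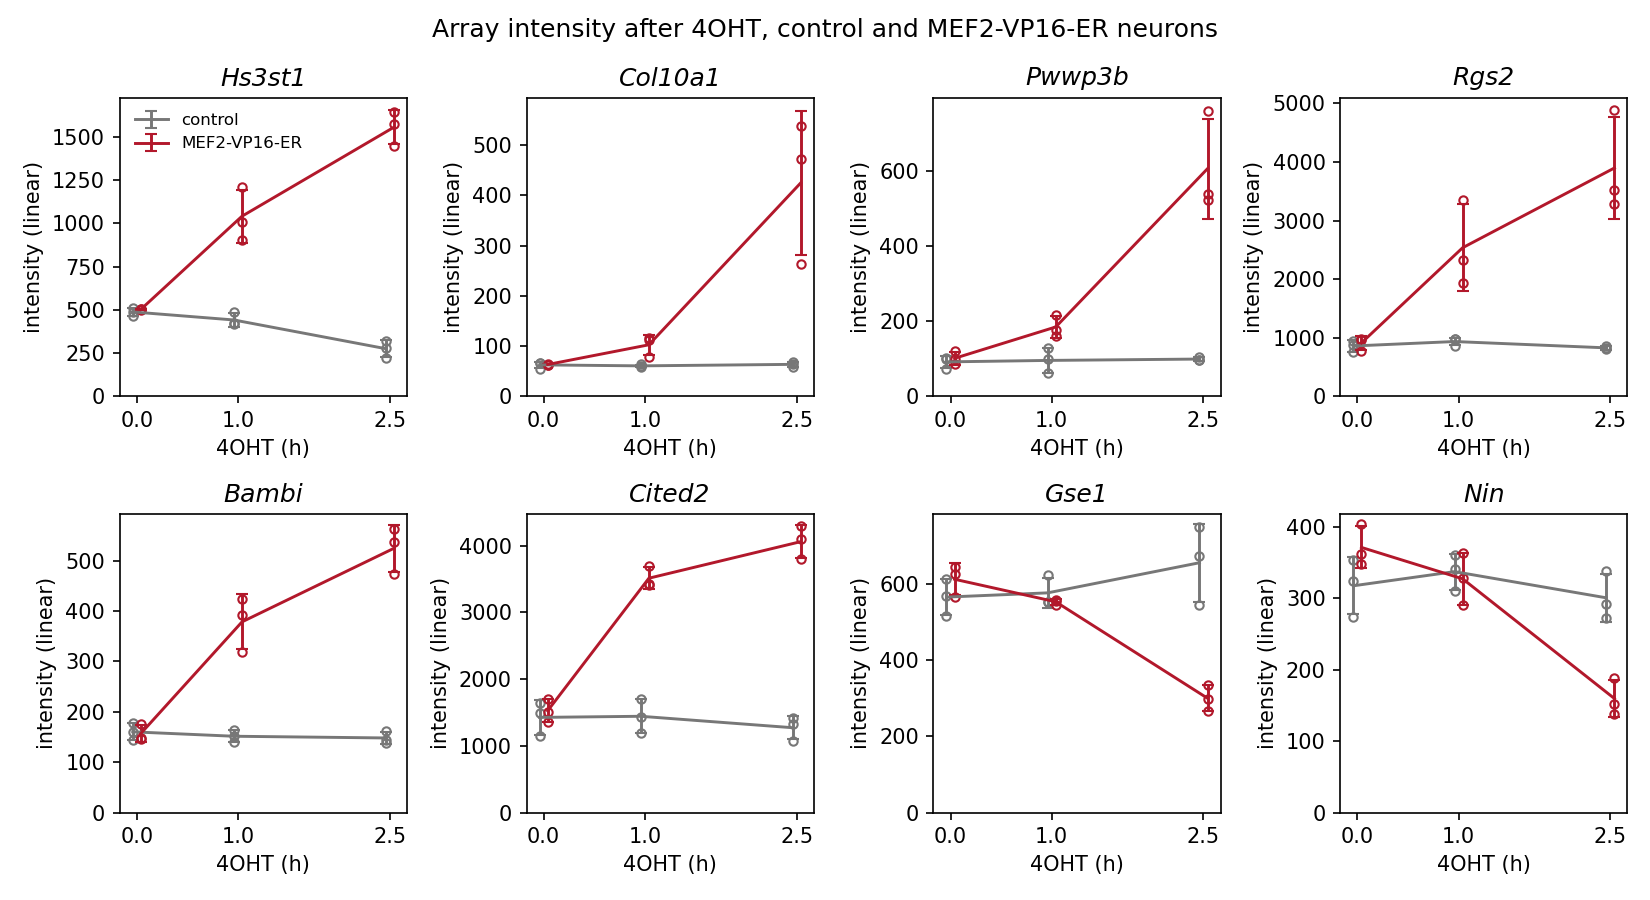
Intensity (linear, as deposited) of Hs3st1, Col10a1, Pwwp3b, Rgs2, Bambi, Cited2, Gse1 and Nin at 0, 1 and 2.5 h of 4OHT in control (grey) and MEF2-VP16-ER (red) neurons; circles are the 3 arrays of a group, and lines with bars are means ± SD. Bambi went from 157 to 378 and 524 in MEF2-VP16-ER neurons.

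**Figure D2:**
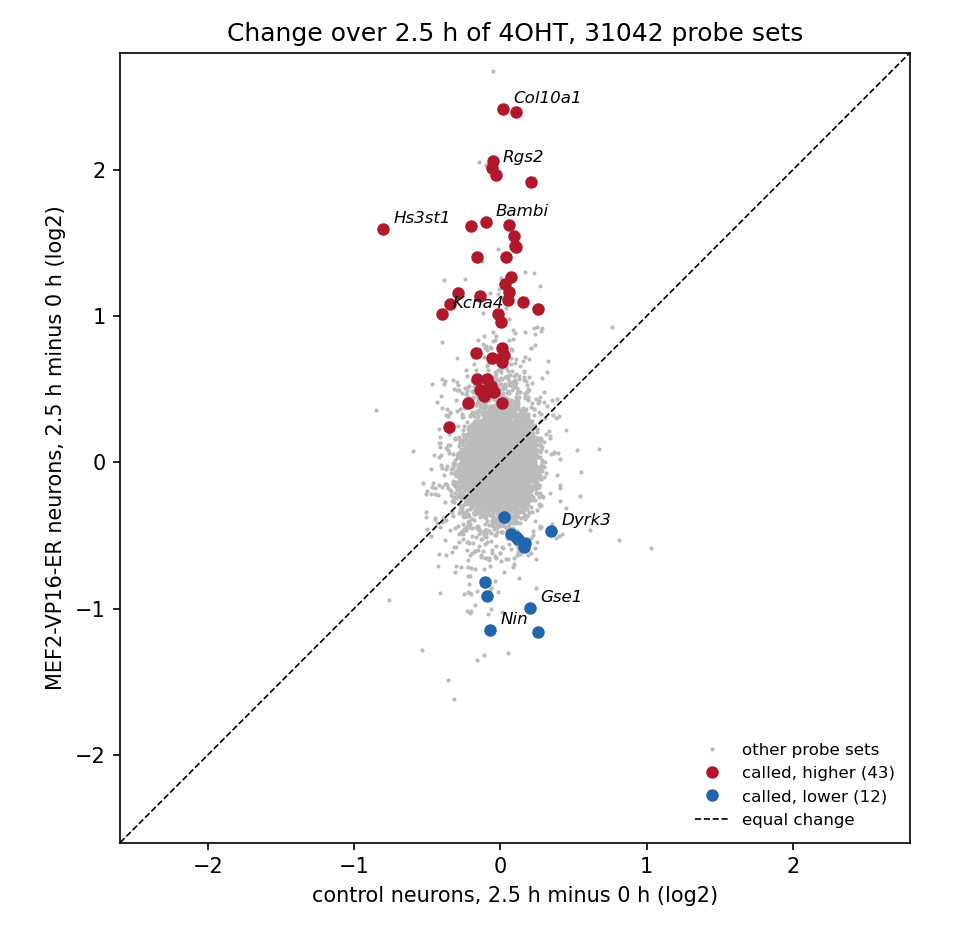
Change from 0 to 2.5 h in control neurons (horizontal, log2) against the change in MEF2-VP16-ER neurons (vertical, log2), 1 point per probe set; the dashed line marks equal change. The 43 probe sets with a higher induction are red and the 12 with a lower one are blue.

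The MEF2 genes themselves and well-known activity-regulated genes gave mixed values at 2.5 h. Nr4a1 was the only gene of this set that changed. Arc was at -0.18 ± 0.17 (adjusted p = 1.00), and the 5 probe sets of Homer1 lay between 0.01 and 0.43. Bdnf, which encodes a neurotrophin, was at 1.63 ± 0.50 (adjusted p = 0.509) and at 0.46 ± 0.16 (adjusted p = 0.715) on its 2 probe sets. With the replicate block the former passed (adjusted p = 0.000131) and the latter did not (adjusted p = 0.0571). The 4 probe sets of Mef2a lay between 0.37 and 0.67 (adjusted p = 0.910 to 1.00), of which those at 0.49 (adjusted p = 0.0271) and 0.67 (adjusted p = 0.0470) passed with the block. Mef2c was at 0.06 and 0.11 and Mef2d at 0.17 and 0.21 on their 2 probe sets each, and Mef2b was at -0.06.

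Fixed lists of genes were compared with all other genes at 2.5 h by limma's camera test. Of 40 measured genes of cell adhesion and axon guidance, 31 were positive (median 0.12): Cdh10, a cadherin, rose by 0.71 ± 0.10, none fell and 39 did not pass. Adjusted over the list alone 5 rose and 1 fell, among them Epha3 (0.63 ± 0.12), Sema6a (0.84 ± 0.18; another of its probe sets rose, by 0.66) and Sema4a (-0.43 ± 0.12). With the replicate block these and the protocadherin genes Pcdh17 (0.67) and Pcdh20 (0.68) passed over all genes, so that 5 rose and 1 fell. The list shifted up (adjusted p = 2.66e-05; adjusted p = 0.295 with an estimated correlation). Of 30 activity-regulated effector genes, Rgs2 and Inhba rose, none fell and 28 did not pass; adjusted over the list alone 3 rose and 1 fell, with Bdnf (1.63) and Sik1 (-0.39) added. That list had a median of 0.11 with 18 positive members (adjusted p = 0.00455; adjusted p = 0.520 with an estimated correlation). Of 8 neuronal MEF2 targets taken from the literature, which are not independent evidence since part of the list came from published work on MEF2 in hippocampal neurons, only Nr4a1 rose and none fell; adjusted over the list alone 2 rose, with Bdnf added. Pcdh10, a protocadherin in that list, was at 0.70 ± 0.30, and the list's median was 0.17 with 5 positive (adjusted p = 0.00746; adjusted p = 0.295 with an estimated correlation).

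Among 8 genes of the MEF2 family and class IIa histone deacetylases none changed, and adjusted over the list alone 1 rose, Hdac5 (0.58 ± 0.15). The median was 0.17 with 6 positive (adjusted p = 0.00222; adjusted p = 0.295 with an estimated correlation). Of 40 muscle genes known as MEF2 targets none changed, and adjusted over the list alone 2 rose, the myosin light chain gene Myl1 (0.45 ± 0.09) and the coactivator gene Ppargc1a (0.69 ± 0.17), both of which passed over all genes with the replicate block. Their median was 0.06 with 29 positive (adjusted p = 0.00746; adjusted p = 0.462 with an estimated correlation). In the other direction, all 19 measured genes of cholesterol synthesis and SREBP targets were negative (median -0.35), none passed over all genes and none when adjusted over the list alone. Mvd was at -0.67 ± 0.70, Stard4 at -0.62 ± 0.68, Sc5d at -0.56 and Insig1 at -0.53 (list adjusted p = 0.00455; adjusted p = 0.884 with an estimated correlation). The arrays of replicate 3 were 0.67 log2 units higher than those of replicates 1 and 2 over the same cholesterol genes. Of 9 excitatory neuron markers none changed, and adjusted over the list alone 2 fell, the transcription factor genes Neurod2 (-0.75 ± 0.15) and Neurod6 (-0.55 ± 0.17), both of which passed over all genes with the block. Those markers had a median of -0.11 with 4 positive (adjusted p = 0.0463; adjusted p = 0.462 with an estimated correlation).

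Of the 26 lists, these 7 passed at 2.5 h, 5 up and 2 down. With the replicate block 11 passed, the additions being microglia markers (up, adjusted p = 0.0121), heat shock genes (down, adjusted p = 0.0348), oligodendrocyte markers (down, adjusted p = 0.0427) and astrocyte markers (up, adjusted p = 0.0465). These 4 additions had adjusted p = 0.299 to 0.532 with the block and an estimated correlation. With the block and an estimated correlation, a setting chosen after the values were seen, cell adhesion (adjusted p = 0.0180), effector genes (adjusted p = 0.0180) and the literature targets (adjusted p = 0.0327) passed and the other 23 lists did not. Without replicate 1 the effector list (adjusted p = 0.0524) and the muscle list (adjusted p = 0.0650) lost the call, and heat shock genes gained it (adjusted p = 0.0378). Without replicate 2 the literature list (adjusted p = 0.0667), cholesterol genes (adjusted p = 0.119) and excitatory markers (adjusted p = 0.0875) lost it. Without replicate 3 the muscle list (adjusted p = 0.109), the MEF2 family list (adjusted p = 0.0624) and excitatory markers (adjusted p = 0.313) lost it, while immediate early genes (adjusted p = 0.000651), oxidative phosphorylation (adjusted p = 0.000448) and oligodendrocyte markers (adjusted p = 0.00119) gained it. Cell cycle genes also passed without replicate 3, downward (median -0.08, adjusted p = 0.0256), against a positive median with all arrays.

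The remaining 19 lists did not pass at 2.5 h. Of 27 immediate early transcription factor genes, Nr4a1 and Nr4a3 (0.63 ± 0.10) rose and none fell; adjusted over the list alone 3 rose and 1 fell, with Klf6 (0.89 ± 0.18) and Srf (-0.47 ± 0.14) added (median 0.05, adjusted p = 0.0800). With the replicate block Klf6, Srf, Nr4a2 (1.00), Egr1 (-0.80) and Klf10 (-0.79) also passed over all genes, for 4 rises and 3 falls in that list. Of 14 MAP kinase phosphatase and Ras-MAPK feedback genes, Spry1 rose; adjusted over the list alone 2 rose and 1 fell, with Dusp14 (0.46) and Errfi1 (-0.52) added (median -0.01, mean 0.03, test up, adjusted p = 0.915). Of 27 voltage-gated potassium channel genes, Kcna4 rose, and no other did when adjusted over the list alone; Kcnv1 (0.51) passed with the block (median -0.03, mean 0.05, test up, adjusted p = 0.624). No member changed, over all genes or adjusted over the list alone, among 35 glutamate receptor and scaffold genes (median 0.00, adjusted p = 0.624), 12 GABA receptor and inhibitory synapse genes (0.03, adjusted p = 0.630), 16 estrogen receptor targets (0.03, adjusted p = 0.630) and 21 heat shock genes (-0.13, adjusted p = 0.150). In the last of these Hspb1 was at a fold of 2.84, and it passed with the replicate block (adjusted p = 0.000685). The same held for 24 interferon response genes (-0.02, adjusted p = 0.775), 15 p53 targets (-0.07, adjusted p = 0.303), 45 oxidative phosphorylation genes (0.03, adjusted p = 0.302) and 24 cell cycle genes (0.05, adjusted p = 0.977). It also held for markers of astrocytes (13 measured, 0.05, adjusted p = 0.212), oligodendrocytes (12, -0.16, adjusted p = 0.264), microglia (14, 0.13, adjusted p = 0.0837) and fibroblasts (14, 0.07, adjusted p = 0.333). In 4 further lists without a changed gene, median, mean and test differed in sign: synaptic vesicle genes (28 measured, median -0.003, mean 0.003, test down, adjusted p = 0.930), NF-kappaB genes (24, 0.006 and -0.01, down, adjusted p = 0.930), inhibitory neuron markers (10, 0.02 and -0.03, up, adjusted p = 0.977) and endothelial markers (12, 0.004 and 0.003, down, adjusted p = 0.977).

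**Figure D3:**
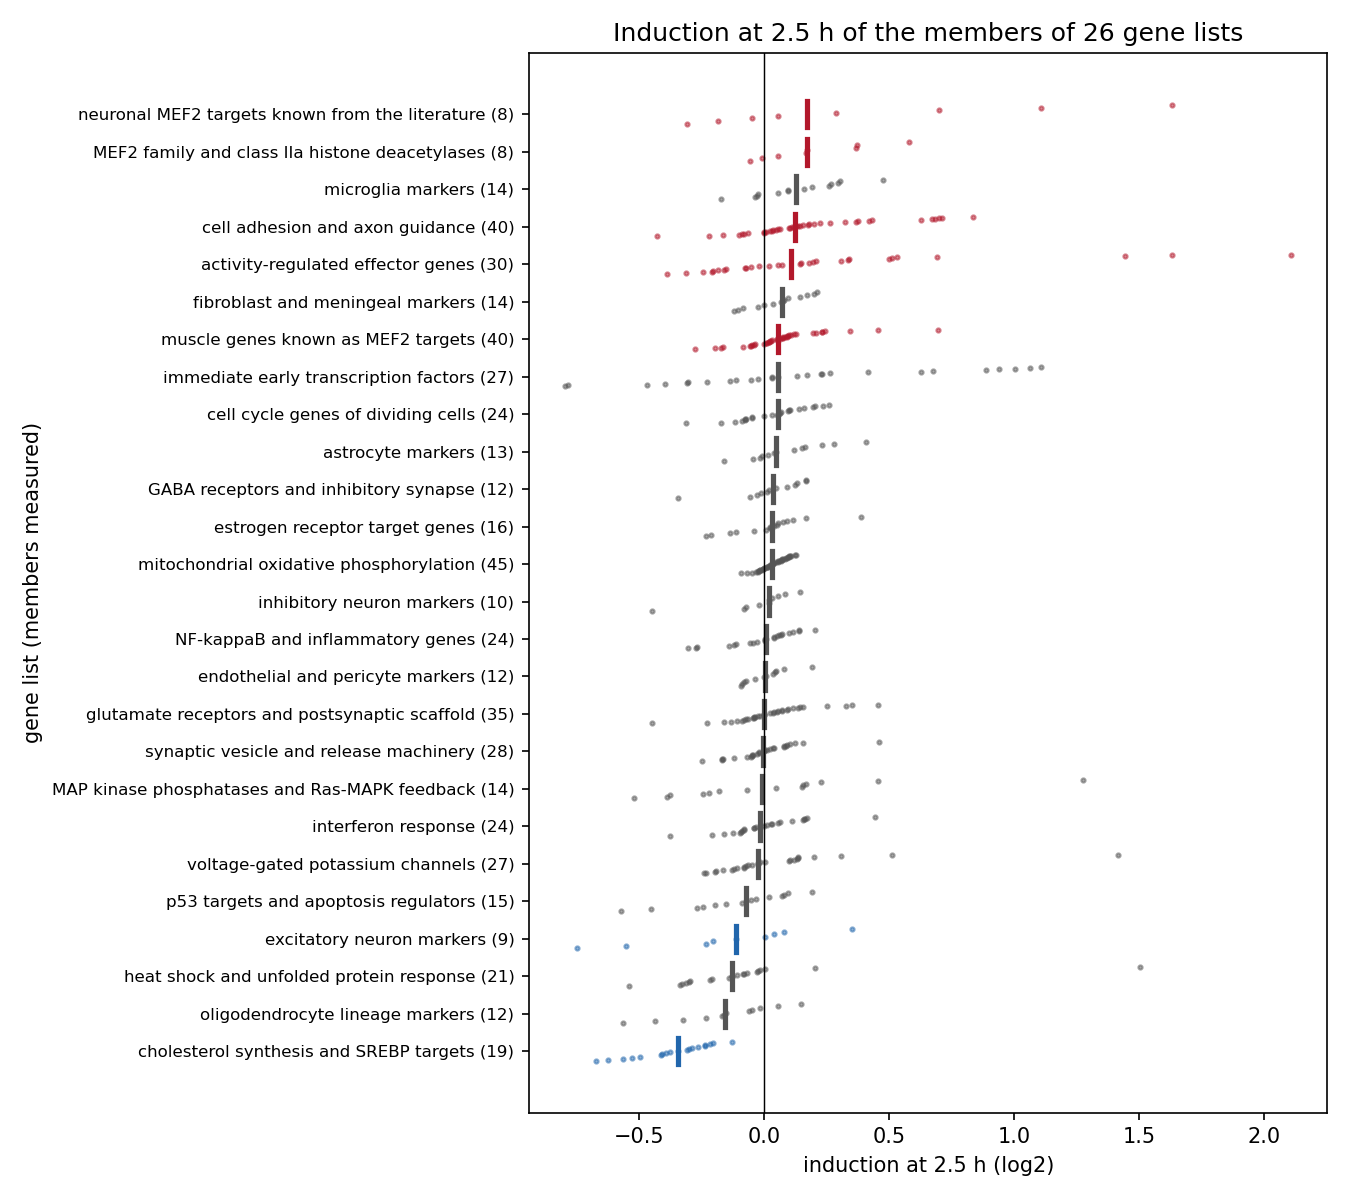
Induction at 2.5 h (log2) of the measured members of the 26 gene lists, 1 dot per gene, with bars at the list medians. Lists that passed upward are red and those that passed downward are blue; all 19 cholesterol genes lie below 0.

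At 1 h the same comparison asked which genes changed early. Without the replicate block, which is not used at 1 h because the pairing check failed there, Bambi was the only gene that changed, with a rise of 1.26 ± 0.15 (SE, 3 arrays in each of 4 groups; adjusted p = 0.0200), and its intensity was already 378 ± 54.7 (SD, n = 3) in MEF2-VP16-ER neurons. Rgs2 (1.30 ± 0.25), Spry1 (1.10), Klf6 (0.99 ± 0.18) and Nr4a1 (0.86 ± 0.19) did not pass over all genes. In the fit with the block, given only as an alternative at 1 h, Klf6 passed (limma adjusted p = 0.00371) and Rgs2, Spry1 and Nr4a1 did not. Its further calls, Cited2 and Hs3st1 among them, are given under the processing settings. That Bambi was the only change at 1 h therefore depends on leaving the replicate number out. Limma called 1 probe set, and 1459 had unadjusted p under 0.05. The call of Bambi was lost without control 0 h replicate 1 (adjusted p = 0.0972) or replicate 2 (adjusted p = 0.0972), control 1 h replicate 2 (adjusted p = 0.0994) or replicate 3 (adjusted p = 0.101), MEF2-VP16-ER 0 h replicate 1 (adjusted p = 0.113) or replicate 3 (adjusted p = 0.115), and MEF2-VP16-ER 1 h replicate 1 (adjusted p = 0.0738) or replicate 3 (adjusted p = 0.103). Its estimate stayed between 1.17 and 1.37, and without MEF2-VP16-ER 1 h replicate 2 the count was 2.

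Among the lists at 1 h, 4 passed by camera, all with adjusted p = 0.902 with an estimated correlation. Immediate early transcription factor genes shifted up (27 measured, 16 positive, median 0.11, adjusted p = 0.0339); none changed over all genes, and adjusted over the list alone 2 rose, Klf6 and Nr4a1. Microglia markers shifted up (11 of 14 positive, median 0.17, adjusted p = 0.00275), as did muscle genes (25 of 40 positive, median 0.04, adjusted p = 0.0309). Both lists were lower with MEF2-VP16-ER than in control neurons before 4OHT, with medians of similar size (below). The same 0 h arrays enter these shifts. Oxidative phosphorylation genes shifted down, with 4 of 45 positive (median -0.09, adjusted p = 0.0309). Without replicate 2 all 4 lists lost the call (adjusted p = 0.134 to 0.166), without replicate 1 the immediate early list lost it (adjusted p = 0.0949), and without replicate 3 oxidative phosphorylation lost it (adjusted p = 0.176). Heat shock genes (adjusted p = 0.0105) and fibroblast markers (adjusted p = 0.0333) gained it without replicate 1, and effector genes (adjusted p = 0.0147) and cholesterol genes (adjusted p = 0.00635) without replicate 3, as did cell cycle genes, downward (median -0.12, adjusted p = 0.0381), against a median of 0.08 with all arrays.

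The difference between the inductions at 2.5 h and 1 h asked where the induction differed between the times. It was higher at 2.5 h for Col10a1 (1.80 ± 0.26, SE, 3 arrays in each of 4 groups; adjusted p = 0.0220), Hs3st1 (1.24 ± 0.16, adjusted p = 0.00801), Gask1b (1.06 ± 0.13, adjusted p = 0.00600), Cdh10 (0.86 ± 0.10, adjusted p = 0.00292) and Numb (0.71 ± 0.11, adjusted p = 0.0297), an inhibitor of Notch signalling. It was lower for Gse1 (-1.03 ± 0.15, adjusted p = 0.0216). The intensity of Cdh10 in MEF2-VP16-ER neurons was 2233 at 1 h and 3863 at 2.5 h. Limma called 13 probe sets, 12 higher and 1 lower, with 1216 at unadjusted p under 0.05; with the replicate block the count was 124 (104 higher, 20 lower). Hs3st1, Gask1b and Cdh10 kept the call whichever single array was left out, and Col10a1, Numb and Gse1 kept it in 4 of 12 fits. Without all arrays of replicate 2, however, Col10a1 was the only call (limma adjusted p = 0.00775), and Hs3st1, Gask1b and Cdh10 lost theirs. The count was 6 without control 1 h replicate 1, MEF2-VP16-ER 1 h replicate 1 or MEF2-VP16-ER 1 h replicate 2, 7 without control 2.5 h replicate 3, and 8 without MEF2-VP16-ER 1 h replicate 3 or MEF2-VP16-ER 2.5 h replicate 3.

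Within MEF2-VP16-ER neurons alone, 4OHT for 2.5 h was compared with 0 h. The genes listed next were taken from those named for the induction at 2.5 h. Outside that set Fgl2 rose more than any of them (2.68), and Sstr2 (-1.62), Inhbb (-1.32) and Cxcr4 (-1.29) fell more (see the other observations). Col10a1 (2.41, adjusted p = 7.74e-06; n = 3 against 3), Pwwp3b (2.40, adjusted p = 1.74e-05), Rgs2 (2.06), Ptpn21 (1.97), Opn3 (1.92), Bambi (1.64, adjusted p = 1.86e-06), Hs3st1 (1.60, adjusted p = 4.67e-06) and Gbx2 (1.55) rose, and Nin (-1.15) and Gse1 (-0.99) fell. Limma called 245 probe sets, 157 higher and 88 lower, or 104 genes that rose and 56 that fell; 1919 had unadjusted p under 0.05. Of the 43 probe sets with a higher induction 42 were also called here, and of the 12 with a lower one 11. With the replicate block the count was 724 (414 higher, 310 lower), and it was 136 without MEF2-VP16-ER 0 h replicate 2, 134 without MEF2-VP16-ER 0 h replicate 3 and 151 without MEF2-VP16-ER 2.5 h replicate 3.

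After 1 h in MEF2-VP16-ER neurons, 8 genes rose and 1 fell. Rgs2 rose by 1.43 and 1.41 on its 2 probe sets (adjusted p = 0.00356; n = 3 against 3), Cited2 by 1.20 and 1.44, Bambi by 1.18 (adjusted p = 0.000490), Spry1 by 1.05 (adjusted p = 0.0127), Hs3st1 by 1.02 (adjusted p = 0.00356), Nr4a1 by 1.01 (adjusted p = 0.00779), Klf6 by 0.96 (adjusted p = 0.00779) and Sgk1, a kinase gene, by 0.62 (adjusted p = 0.00356). Hes1, a transcriptional repressor downstream of Notch, fell (-1.04 ± 0.13, adjusted p = 0.00356). Klf6, Sgk1 and Hes1 were named after the values were seen. Limma called 11 probe sets, 10 higher and 1 lower, and 1293 had unadjusted p under 0.05; without MEF2-VP16-ER 0 h replicate 3 the count was 7. Of the 10 higher calls 9 were also higher at 2.5 h, where 0.0506 were expected by independence, and the 1 lower call was shared (0.00283 expected). Part of the excess may come from the 0 h arrays used on both sides: over 20 simulations without changed genes the correlation across probe sets was 0.499, against 0.556 in the data. The covariance differed more, at 0.00380 in the simulations against 0.00829 in the data. Shared calls (0 in the simulations) cannot measure that part, since no gene was changed in them.

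In control neurons no gene changed at 2.5 h or at 1 h. Limma called 0 probe sets at 2.5 h, where 667 had unadjusted p under 0.05, and 0 at 1 h, where 840 did. The lowest adjusted p at 2.5 h was 0.137, for Hs3st1 (-0.80 ± 0.11, n = 3 against 3), which passed with the replicate block as the only call (adjusted p = 0.0130) and without control 2.5 h replicate 1 (-0.92, adjusted p = 0.0381). All 19 cholesterol genes were positive at 2.5 h (median 0.20, camera adjusted p = 0.0141; adjusted p = 0.869 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone. The cholesterol list lost the call without replicate 1 (adjusted p = 0.133) and without replicate 2 (adjusted p = 0.257). Without replicate 3 the call was gained by immediate early genes (median -0.09 against 0.04 with all arrays, adjusted p = 0.0452), MAPK feedback genes (adjusted p = 0.00337), oxidative phosphorylation (adjusted p = 3.20e-05), cell cycle genes (adjusted p = 0.0137) and oligodendrocyte markers (adjusted p = 0.00897). The block gave 8 lists, the additions being cell cycle genes (up, adjusted p = 0.000258) and, downward, astrocyte markers (adjusted p = 0.000993), cell adhesion genes (adjusted p = 0.00116), microglia markers (adjusted p = 0.0201), GABA receptor genes (adjusted p = 0.0390), MAPK feedback genes (adjusted p = 0.0390) and excitatory markers (adjusted p = 0.0489). None of the 8 passed with the block and an estimated correlation (adjusted p = 0.290 to 0.483).

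Before 4OHT, MEF2-VP16-ER neurons were compared with control neurons to ask whether the constructs differed without the ligand. No gene changed: limma called 0 probe sets. However, 2736 had unadjusted p under 0.05, of which 1081 were higher. The 1552 expected for uniform p values is no sound yardstick here (above), but 2736 was more than in any other comparison. The absence of calls therefore does not show that the constructs were alike before 4OHT. The lowest adjusted p was 0.426, for the axon guidance receptor gene Robo2 (0.48 ± 0.12, n = 3 against 3). The block gave 1 call, that of the growth factor gene Kitlg (0.40, adjusted p = 0.00887), named after the values were seen. By camera 4 lists were lower, each with adjusted p = 0.850 with an estimated correlation and no member passing over all genes. They were microglia markers (1 of 14 positive, median -0.15, adjusted p = 0.000989), muscle genes (14 of 40 positive, median -0.04, adjusted p = 0.00948), endothelial markers (2 of 12 positive, adjusted p = 0.0480) and fibroblast markers (4 of 14 positive, median -0.07, adjusted p = 0.0480). Adjusted over the list alone, the fibroblast genes Col5a1 (-0.21) and Pcolce (-0.22) fell. The block added cholesterol genes (up, adjusted p = 0.000131), heat shock genes (up, adjusted p = 0.00179) and cell cycle genes (down, adjusted p = 0.0396), none of which passed with the block and an estimated correlation (adjusted p = 0.528, 0.471 and 0.658). Without replicate 1 fibroblast markers lost the call (adjusted p = 0.0816), and heat shock genes (adjusted p = 0.00209), p53 targets (adjusted p = 0.0313) and astrocyte markers (adjusted p = 0.0185) gained it. Muscle genes (adjusted p = 0.109) and fibroblast markers (adjusted p = 0.148) lost it without replicate 2; without replicate 3 endothelial markers lost it (adjusted p = 0.195) and cholesterol genes gained it (adjusted p = 0.000196).

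The 3'-to-5' signal of GAPDH transcripts, a measure of RNA integrity, was 0.072 log2 units higher at 2.5 h than at 0 h in MEF2-VP16-ER neurons and 0.12 higher at 1 h. At 0 h it was lower with MEF2-VP16-ER than in control neurons (-0.059). Each of these 3 comparisons, of 15 over 3 transcripts, had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow; the other 12 had exact permutation p of 0.3 to 1. These p values leave the replicate numbers out. Beta-actin at 0 h was lower with MEF2-VP16-ER in each of the 3 replicates (1.17, 1.23 and 0.91, against 1.31, 1.33 and 1.06 in control neurons). Hexokinase at 0 h was lower in replicates 1 and 3 and higher in replicate 2. Replicate 3 differed from replicates 1 and 2 over cell cycle genes of dividing cells, where 23 of 24 members were higher (median difference 0.79). Other lists with 1 sign of difference in all 6 groups included oligodendrocyte markers (0.39), oxidative phosphorylation genes (0.17, 43 of 45 higher), immediate early transcription factor genes (-0.34), heat shock genes (-0.32), excitatory neuron markers (-0.24), the literature MEF2 targets (-0.23), microglia markers (-0.19), cell adhesion genes (-0.18), fibroblast markers (-0.14) and effector genes (-0.13).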

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

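The tests of intensity-matched probe sets and all tests of the cholesterol genes were chosen only after the result was seen. So was the tally of regroupings that kept the treated arrays together. The other tests in this part were written before.

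Several responses differed between times or between constructs, and each difference was itself tested. The induction at 2.5 h minus that at 1 h was 1.80 for Col10a1, 1.24 for Hs3st1, 1.06 for Gask1b, 0.86 for Cdh10, 0.71 for Numb and -1.03 for Gse1. In control neurons the change at 2.5 h was opposite to that in MEF2-VP16-ER neurons for Kcna4 (-0.40 against 1.02), Nr4a3 (-0.22 against 0.41), Hs3st1 (-0.80 against 1.60) and Dyrk3 (0.34 against -0.47). These 4 genes were picked because their induction passed and their groups did not overlap in either construct, so that pass adds no support. The induction tests whether the 2 changes differ, not whether control neurons moved the other way. The change in control neurons alone passed for none of them without the replicate block; for Hs3st1 it passed with the block (adjusted p = 0.0130) and without control 2.5 h replicate 1 (adjusted p = 0.0381).

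The number of calls was compared with that of regrouped arrays. For the 3 against 3 comparisons 10 splits are too few for a share under 0.05. MEF2-VP16-ER at 2.5 h against 0 h called 245 probe sets and at 1 h 11, with 0 as the highest count of any other split in each, so only the real grouping, 1 of 10, reached the real count. In control neurons at 2.5 h, in control neurons at 1 h and between constructs at 0 h the real count was 0, which 10 of 10 splits reach by construction, so the splits say nothing about these 3 comparisons.

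For the inductions, 100 regroupings within replicate numbers were used, the real grouping included. The rule written before took a share of 0.05 or more as what chance would give. By that rule alone chance stays open at 2.5 h and at 1 h. The tally of arrays kept together, given next, was added afterwards. At 2.5 h 5 of 100 called at least the real 55, with 89 as the highest other. All 5 kept the 3 MEF2-VP16-ER arrays at 2.5 h in 1 group, as 9 of the 100 did, so they still held the difference under test and their share does not measure chance; the highest count with these arrays parted was 20. At 1 h 6 of 100 called at least the real 1 (highest other 5), all 6 with the MEF2-VP16-ER 1 h arrays together, and the highest count with them parted was 0. For the difference between the times 3 of 100 called at least the real 13. That share is under 0.05, but for the same reason it does not measure chance either. Of these, 2 kept the MEF2-VP16-ER 2.5 h arrays together, the real grouping among them. A regrouping that parted them called 42, over 3 times the real count, and the reason for that was not tested.

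The probe sets that fell at 2.5 h were tested against processing causes. The 8351 uncalled probe sets of similar level had a median induction of -0.0129 (interquartile range -0.104 to 0.0768), so no general lowering was seen at these levels. Array medians lay close together as deposited, and the median induction over all probe sets was 0.0037. A value near 0 was therefore likely beforehand, and the test cannot decide on a normalization effect in the 12 falls themselves. With the 3'-to-5' signals of the control transcripts as covariates the median of the 12 falls was -0.769 (median SE of a probe set 0.132), against -0.726 before. The adjustment thus did not shrink the falls. Its slopes came from differences within groups, with no term for the replicate number. Within groups, replicate 3 stood apart both in the beta-actin and GAPDH signals and in many genes (below). The slopes may therefore mix RNA integrity with replicate differences, and the test cannot decide on RNA integrity as a cause. With these covariates 7 of the 12 falls and 37 of the 43 rises were still called.

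Replicate 3 stood apart from replicates 1 and 2, and the first component, which separated it, held 52.8% of the residual variance. The largest difference in a cell-type list was 0.786, in cell cycle genes, so a different mix of cells could be part of it. The 3'-to-5' signal of beta-actin was lower in replicate 3 in 6 of 6 groups (-0.258, SD 0.173 over groups), as was that of GAPDH (-0.0801), so RNA integrity may also differ; for hexokinase it was -0.0665. These are comparisons of 1 replicate number with 2 others, so no p is given. Both of these stay open.

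The cholesterol genes were lower in the induction at 2.5 h. Their median in MEF2-VP16-ER neurons alone was -0.144 with 19 of 19 below 0, which argues against low control arrays at 0 h as a likely sole cause. At 0 h the list mean was 11.34 ± 0.34 log2 units (SD, n = 3) with MEF2-VP16-ER and 11.14 ± 0.36 in control neurons. High MEF2-VP16-ER arrays at 0 h would also give a negative median, and this test cannot exclude them. Relabelling time within constructs, which leaves the difference between replicates in, gave an exact permutation p of 0.325 for the list mean, so members that move together between arrays stay open. Within replicates 1, 2 and 3 the induction was -0.472, -0.436 and -0.197, with MEF2-VP16-ER neurons down and control neurons up in each. Relabelling within replicate numbers as well gave an exact permutation p of 0.0313 (64 relabellings), the smallest possible and 1 of 26 lists, so a shift and chance cannot be told apart by that test.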

How the results depend on the processing

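The block with an estimated correlation was the only setting chosen after the result was seen; the cause of the changes below was not tested, except that leaving arrays out or fitting fewer groups leaves less information.

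At 2.5 h the 55 induction calls became 291 with the replicate block, 32 with only the contrast's groups in the fit (28 higher, 4 lower) and 397 at the same time point without the 0 h difference (295 higher, 102 lower); leaving out arrays or replicates gave 5 to 64. At 1 h the 1 call became 2 with median centring, with probe sets above the median level, with trend and robust variances or with 1 probe set per gene, and 3 with quantile normalization. It became 0 with only the contrast's groups, 19 without the 0 h difference (17 higher, 2 lower), 9 with the block (8 higher, 1 lower) and 0 to 2 with arrays left out. The block is given here for 1 h although the pairing check failed for replicate 2 (correlation 0.068); it added Cited2 (adjusted p = 0.000654), Hs3st1 (0.00248), Klf6 (0.00371), Nr4a2 (0.0257) and Klf5 (0.0498) as higher and Mycn (0.0498) as lower. The 13 calls of the difference between times became 7 above the median level, 1 with only the contrast's groups, 124 with the block and 0 to 13 with arrays left out.

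In MEF2-VP16-ER neurons the 245 calls at 2.5 h became 724 with the block, 75 with only the contrast's groups (56 higher, 19 lower) and 52 to 225 with arrays left out. The 11 calls at 1 h became 58 with the block (48 higher, 10 lower), 4 with only the contrast's groups and 1 to 15 with arrays left out. In control neurons at 2.5 h the 0 calls became 1 with the block and 0 to 1 with arrays left out; at 1 h every setting gave 0. At 0 h the block gave 1 call and every other setting 0.

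Of the lists, 7 passed at 2.5 h, 4 at 1 h, 1 in control neurons at 2.5 h and 4 at 0 h. With an estimated correlation these became 0 in each; with the block 11, 7, 8 and 7; with the block and an estimated correlation 3, 0, 0 and 0. Above the median level the control lists became 2 (1 up, 1 down), those at 2.5 h 7 (6 up, 1 down, excitatory markers lost and immediate early genes gained), those at 1 h 6 (6 up, 0 down, oxidative phosphorylation lost) and those at 0 h 3; microglia and endothelial markers had too few members there to be tested. With the mean over probe sets the lists became 9 at 2.5 h and 3 at 0 h. Leaving out a replicate number gave 4 to 8 at 2.5 h, 0 to 6 at 1 h, 0 to 6 in control neurons and 2 to 6 at 0 h. Cell cycle genes, which did not pass with all arrays, turned downward and passed without replicate 3 at 2.5 h (median -0.0771; -0.0771 to 0.136 as each replicate number was left out) and at 1 h (median -0.119; -0.119 to 0.202); the cause was not tested. In control neurons at 2.5 h, immediate early genes passed downward without replicate 3 (median -0.0922), where their median with all arrays was 0.0425 and their test already pointed down. No other list or gene that passed in either setting turned its direction. Of the genes always named, the block changed the call of Bdnf and of 2 Mef2a probe sets and no other.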

Other observations

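Within MEF2-VP16-ER neurons further genes changed at 2.5 h whose induction did not pass without the replicate block; the 6 named genes with the largest rises and the 6 with the largest falls are given, chosen after the values were seen. Fgl2, which encodes a fibrinogen-like protein, rose by 2.68 ± 0.47 log2 units (SE, n = 3 against 3; adjusted p = 0.0106), from an intensity of 53.8 to 435; its induction was 2.73 ± 0.67 (adjusted p = 0.208; adjusted p = 0.000125 with the replicate block). Synpo2 (1.26 ± 0.18, adjusted p = 0.00192), the transcription factor gene Nfil3 (1.19 ± 0.18, adjusted p = 0.00356), Fam43a (1.16), Mylip (1.04) and Gpr37 (1.02) also rose. With the block the induction passed for Synpo2 (adjusted p = 0.0207), Nfil3 (adjusted p = 0.00423), Fam43a (adjusted p = 0.00557), Mylip (adjusted p = 0.00341) and Gpr37 (adjusted p = 0.000637).

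The somatostatin receptor gene Sstr2 fell in the same comparison (-1.62 ± 0.24, adjusted p = 0.00269), from an intensity of 500.4 to 158. Inhbb, an activin subunit gene (-1.32 ± 0.27, adjusted p = 0.0292), the chemokine receptor gene Cxcr4 (-1.29 ± 0.17, adjusted p = 0.00142), Arrdc4 (-1.04), Runx1t1 (-1.03) and Slc35d3 (-1.01) fell too; Cxcr4 was at -0.53 in control neurons, where it did not pass. With the block the induction passed for Sstr2 (adjusted p = 0.000216), Inhbb (adjusted p = 0.000216), Arrdc4 (adjusted p = 0.00900) and Runx1t1 (adjusted p = 0.0356), and not for Cxcr4 (adjusted p = 0.107) or Slc35d3 (adjusted p = 0.0867).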
